A study of Rattus norvegicus with 7 samples.

How the data were processed

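Liver RNA of young (2 months) and old (18 months) male rats was measured on 7 two-channel arrays of 2 platforms, with young RNA in channel 1 on 4 arrays and in channel 2 on 3. The deposited tables hold 1 log ratio per probe and array, with blanks for probes without a value. The scanner, the dyes, the background correction, the normalization method and the filter behind the blanks are not given in the sources used here. On the 3-array platform the deposited values themselves show that the authors took log2 of a ratio kept to 3 decimals (steps of 0.001) and shifted each array by 1 constant, with the sign turned on array 2. On the 4-array platform the deposited values show no such steps, the base of the logarithm is not stated, and it was taken as log2. The folds of that platform rest on this reading. Without intensities, dim spots could not be filtered and no brightness-dependent correction could be made, so that such a bias, where the authors left it, stays in the ratios.

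Arrays were grouped by the ages the labels give for their channels, and array numbers are those in the sample titles. Each array was centred on its median. On the 3-array platform 96 probe identifiers occupy 2 rows each. All 169 values given in both rows were identical, and each identifier was counted once. Identifiers of the platforms were matched by their text after the leading row number of the 3-array platform; whether the same sequence was printed was not tested. The rat gene table (assembly GRCr8, 47357 genes) held 0 of the identifiers among its identifiers, symbols, synonyms and accessions. The 34 gene lists prepared for the comparisons could therefore not be tested, probes are not named by gene, and the steps planned per gene were done per probe.

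The gene lists, the tests, their thresholds, the rule for named probes and the direction rule were set before the data were examined; the alternatives added later are named at the end. A mean correlation between arrays of opposite channel order above 0.3 was read as ratios already turned to a common age direction, below -0.3 as ratios of channel over channel, and between these only arrays of the same channel order were averaged. Each probe's mean ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the probes tested, threshold 0.05), separately for each platform because the tables were made separately. Probes with values on at least 3 of 4 arrays, or on both of arrays 1 and 3, were tested; the plan had asked for all 3 arrays of the 3-array platform, of which the direction rule kept these. The rule for named probes was the largest mean change in each direction among probes past the threshold, measured on every array and on the same side of 0 on all; of the 10 per direction that it gives, 2 per direction are printed, because the identifiers carry no gene name. Correlations between platforms used 100000 permutations of probe labels in R, and the tables were read and summarised per array with Python 3.11.15. The procedure was tested on simulated data with 200 changed probes, the real pattern of blanks and the SDs observed between arrays, in 20 simulations per comparison. On the 4-array platform 39.5%, 76.6% and 94.8% of changes of 1.5-fold, 2-fold and 4-fold were recovered among 3834 probes, with 4.82% of calls false. These simulations draw arrays independently and take SDs observed over few arrays as true spreads.

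The alternatives tried were no centring, quantile and scale normalization, other minimum numbers of arrays, a channel term, the other reading of the direction, arrays of a single channel order, robust eBayes, a fold minimum of 1.5, array weights and leaving out each array. Added after seeing the data were the channel order as a random block, the mean of each channel order as the unit, the centring of identifier blocks, the 3-array platform with all its arrays less array 1 or 3, and, in the comparison of platforms, each array of the 3-array platform alone and the means of all 3.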

Results

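Gene expression in the liver of male rats of 2 months, labelled normal, was compared with that of male rats of 18 months, labelled old, on 7 two-channel arrays. Each array carried young RNA in 1 channel and old RNA in the other, so that every array gave its own ratio between the ages. Young RNA was in channel 1 on 4 arrays (arrays 1, 3, 6 and 7) and in channel 2 on 3 arrays (arrays 2, 4 and 5). Arrays 4 to 7 belonged to a platform with 6240 probes, called here the 4-array platform. Arrays 1 to 3 belonged to a platform with 3168 rows for 3072 probe identifiers, all of which also occurred on the 4-array platform. A ratio was deposited for 4640, 4141, 2966 and 5047 probes on arrays 4, 5, 6 and 7, and for 1931, 1337 and 1924 rows on arrays 1, 2 and 3. The array medians lay between -0.05 and 0.002, and the standard deviation over probes ranged from 0.46 on array 3 to 0.79 on array 6. Spot intensities were not used here, so the precision of a ratio is given by the spread between arrays, and the small number of arrays limits it. The tables used here do not pair the probe identifiers with genes: 0 of them matched the rat gene table, and probes are therefore reported by identifier. The labels do not say whether arrays of a platform came from separate animals, so the p-values measure only the spread between arrays.

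Before any averaging, the ratios of the arrays were compared to see whether they ran the same way. On the 4-array platform arrays of opposite channel order correlated positively across probes, with Pearson's r between 0.55 for arrays 4 and 7 and 0.69 for arrays 5 and 6, and a mean of 0.62. Arrays of the same channel order correlated at 0.83 for arrays 4 and 5 and at 0.82 for arrays 6 and 7. The deposited ratios of this platform were therefore read as already turned to a common direction of age. On the 3-array platform arrays 1 and 2, which had opposite channel orders, correlated at -0.47, arrays 2 and 3 at 0.02, and arrays 1 and 3, which shared a channel order, at 0.08. The mean over its pairs of opposite order, -0.23, lay between the limits of -0.3 and 0.3 set for either reading, so that only arrays 1 and 3 entered the comparison. A feature of the values, looked for after they had been seen, bears on how this platform's ratios were made. Taken as powers of 2 and multiplied by 1 constant per array, 99.9% of the distinct values of array 1 and 100% of those of array 3 were whole multiples of 0.001 within a tolerance of 0.05 steps. For array 2 the same was true of 100% of the values with the sign turned and of 12.8% with the sign as deposited, where chance gives 10%. No source used here says whether a positive ratio means more RNA in old or in young liver. The base of the logarithm on the 4-array platform is not stated either, and folds there rest on reading it as 2. Changes are given below as positive or negative in the deposited direction. If that direction is young over old, every negative change is a higher level in old rats, and if it is old over young, every negative change is a lower level in old rats.

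**Figure D1:**
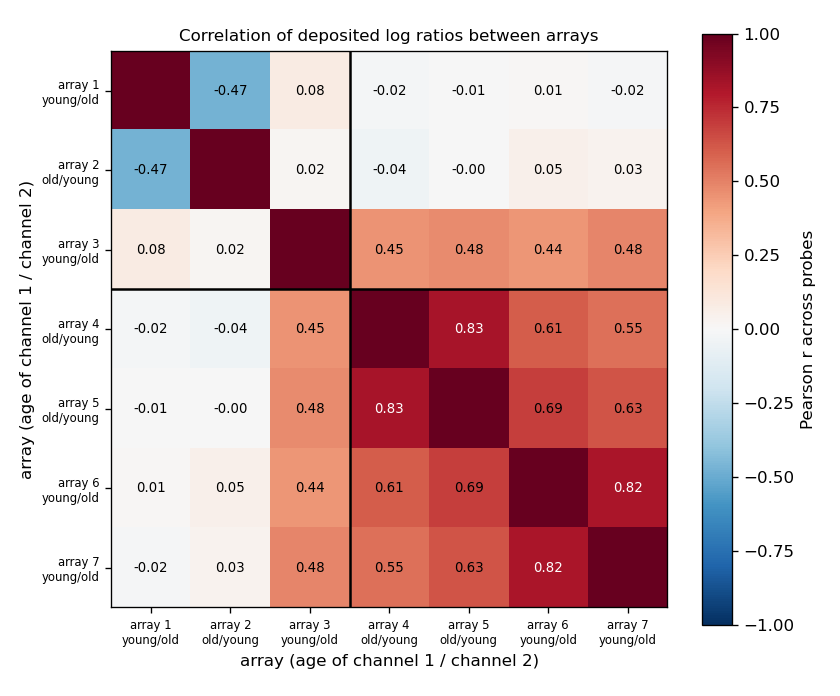
Pearson's r across probes between each pair of the 7 arrays, with the age in channel 1 and channel 2 under each array number and black lines between the 3-array platform (arrays 1 to 3) and the 4-array platform (arrays 4 to 7). Arrays 4 to 7 correlate with one another at 0.55 to 0.83, array 3 correlates with them at 0.44 to 0.48, and arrays 1 and 2 correlate with each other at -0.47.

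On the 4-array platform, a fit that takes the arrays as independent called 801 of 3834 probes measured on at least 3 arrays, or 20.9% (limma, Benjamini-Hochberg adjusted p under 0.05, two-sided). Of these, 446 were positive and 355 were negative. The median size of the change was 0.78 on the log2 scale among the positive probes and 0.66 among the negative ones. A change of at least 2-fold was found for 142 positive and 99 negative probes, and of at least 4-fold for 23 positive and 23 negative probes. Changes of at least 8-fold were found for 5 positive and 11 negative probes. The largest negative changes were those of probe RGIAP58, at -4.28 ± 0.07 (mean log2 ratio ± SD, n = 4, limma adjusted p = 1.613e-06), and of probe RGIAI10, at -4.22 ± 0.38 (n = 4, limma adjusted p = 9.141e-06). They correspond to differences of 19.4-fold and 18.7-fold. The largest positive changes among probes measured on all 4 arrays were those of probe RNABJ21, at 4.69 ± 0.95 (n = 4, limma adjusted p = 1.199e-04), and of probe RGIBA47, at 3.26 ± 1.25 (n = 4, limma adjusted p = 0.00197). They correspond to differences of 25.7-fold and 9.55-fold. The ratio of RGIAP58 lay between -4.38 and -4.20 on the 4 arrays, whereas that of RGIBA47 ranged from 1.83 on array 7 to 4.67 on array 5. Among the 2591 probes measured on all 4 arrays, the ratio lay on the same side of 0 on every array for 1263, or 48.7%. With the agreement seen within each channel order and none between the orders, 30.8% would do so. Fits without 1 array tested probes with values on at least 2 of the others, so the probes tested changed too. The probes called numbered 354 of 4407 without array 5, 474 of 4105 without array 4, 533 of 4683 without array 6, and 645 of 4099 without array 7. Averaging the arrays of a channel order first, so that 2 values per probe entered the fit, called 378 of 4420 tested probes. Of these 378, 345 were among the 801.

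**Figure D2:**
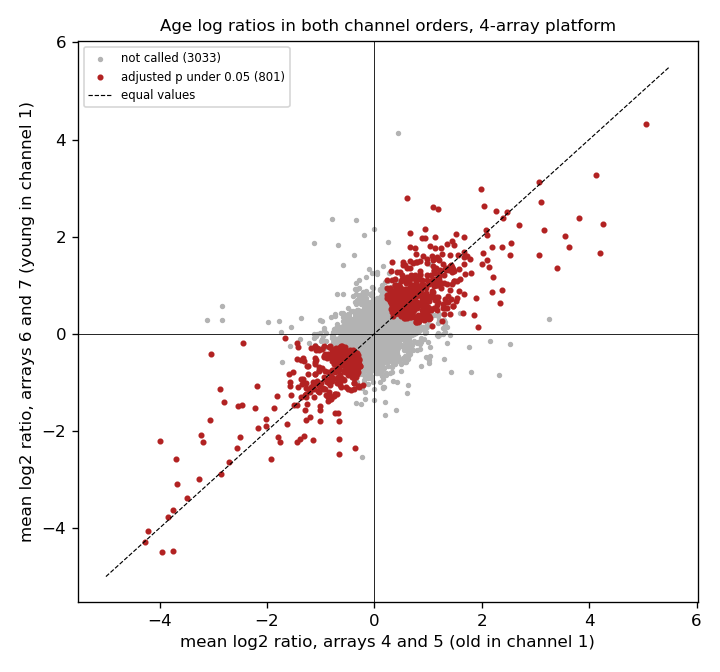
Mean log2 ratio of each tested probe on arrays 4 and 5 (x axis, old RNA in channel 1) against its mean on arrays 6 and 7 (y axis, young RNA in channel 1), with the 801 called probes in red, the others in grey and equal values on the dashed line. The called probes lie in the 2 quadrants of equal sign, which the call itself favours, and the means of all probes measured in both orders correlate at 0.62.

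The same platform shows how far the age ratios differed between the channel orders. Arrays 4 and 5 held 1 order and arrays 6 and 7 the other, so such a difference may also be one between RNA samples. The means of the 2 channel orders correlated at 0.62 across 4420 probes. A term for the channel order was significant for 63 of 3834 probes (limma adjusted p under 0.05, two-sided). Of these, 30 had the higher ratio with young RNA in channel 1 and 33 the lower. At an unadjusted limma p under 0.05 there were 714 probes. Across probes measured in both orders, the median absolute half-difference between the orders was 0.143, against a median absolute mean of 0.246. The half-difference also holds the spread between arrays. Of the 801 probes called for age, 14 were among these 63; calling a mean over both channel orders favours probes on which they are alike, so this overlap does not measure the effect of the channel. For RGIAP58 the mean was -4.27 on arrays 4 and 5 and -4.29 on arrays 6 and 7. For RGIBA47 it was 4.25 on arrays 4 and 5 and 2.26 on arrays 6 and 7. How the channel order was handled moved the count of 801 in both directions. With the order as a fixed term 1319 probes were called for age, and with the order as a random block 522. With each order averaged first, 378 of 4420 tested probes were called, so that this setting also changed the probes tested. The main fit takes the 4 arrays as independent, whereas the random block put the correlation within a channel order at 0.306. Across probes, arrays of the same order correlated at 0.82 and 0.83, against 0.55 to 0.69 between orders. The main fit thus ignores a dependence between arrays, and it called 801 probes against 522 with the random block, which models that dependence. The fixed term sets the mean against the spread within an order only.

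On the 3-array platform, the comparison of arrays 1 and 3 called 1 of 1623 probes (limma, Benjamini-Hochberg adjusted p under 0.05, two-sided). This was probe RGIAN79, at -2.14 ± 0.40 (mean log2 ratio ± SD, n = 2, limma adjusted p = 0.0243), a difference of 4.41-fold. Its ratio was -1.86 on array 1 and -2.42 on array 3, and array 2 gave no value for it. On the 4-array platform the same identifier, without a value on array 6, stood at -1.37 ± 0.33 (n = 3, limma adjusted p = 0.00287). The call was lost with the values as deposited (limma adjusted p = 0.187), with the arrays scaled to a common spread (limma adjusted p = 0.724), and when array 2 was let in for probes with at least 2 values (limma adjusted p = 0.431). Over the alternatives the limma adjusted p ranged from 0.0223 to 0.724. The change itself was not smaller where the call was lost, at -2.14 as deposited, -2.31 with scaling and -2.14 with array 2 let in. At an unadjusted p under 0.05 there were 104 probes, where chance gives 81.2. In simulations of arrays 1 and 3, 18.8% of 4-fold changes and 0.149% of 2-fold changes were recovered, against 94.8% and 76.6% in simulations of the 4-array platform. Each simulated spread for arrays 1 and 3 was an SD of only 2 real values, and such SDs scatter more widely than true spreads. The recovered shares therefore do not give the power of the real fit of arrays 1 and 3. On the 4-array platform, fits of 2 arrays of the same channel order called 1405 probes (arrays 4 and 5) and 593 probes (arrays 6 and 7), so the number of arrays alone does not account for the single call.

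Whether the ratios of the platforms ran together was tested over the identifiers they share. The mean ratio of arrays 1 and 3 correlated with that of arrays 4 to 7 at r = 0.38 across 1489 probes (Spearman's rho 0.19; for Pearson's r, permutation of probe labels, p = 1e-05, the smallest that the permutations can give, and 1.5e-05 adjusted over 6 correlations). Probes are not independent replicates, so this p describes these arrays only. The relation rested on array 3. Array 3 alone correlated with the 4-array mean at r = 0.52 across 1666 probes (permutation, adjusted p = 1.5e-05; rho 0.34). Array 1 alone gave r = -0.02 across 1631 probes (permutation, adjusted p = 0.559; 95% interval -0.06 to 0.03). Array 2 alone gave r = 0.02 across 1154 probes (permutation, adjusted p = 0.559; 95% interval -0.04 to 0.07). Of the called probes of the 4-array platform, 343 had a ratio on array 3 and 253 of them, or 73.8%, had the same sign there (95% exact binomial interval 68.8% to 78.3%, for counting error only). The share was 49.0% of 349 probes on array 1 and 49.8% of 283 probes on array 2. Counted after the values were seen, the 23 negative probes of at least 4-fold included 16 with a ratio on array 3, and all 16 were negative there, with a median of -2.30. Of the 23 positive probes of at least 4-fold, 8 had a ratio on array 3, and 7 of them were positive there, with a median of 0.45. On array 1, 15 of 18 of the negative probes and 3 of 9 of the positive probes had the same sign as on the 4-array platform, with a median of -0.53 in either direction. On array 2, 7 of 17 of the negative probes and 6 of 7 of the positive probes had the same sign, with medians of 0.14 and 0.31. Probe RGIAP58 stood at -2.48 on array 3, at -0.69 on array 1 and at 1.38 on array 2. Probe RGIAI10 stood at -1.76, -0.54 and 1.34 on the same arrays. Probe RGIBA47 stood at 0.24 on array 3 and at 0.26 on array 1, and array 2 gave no value for it.

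**Figure D3:**
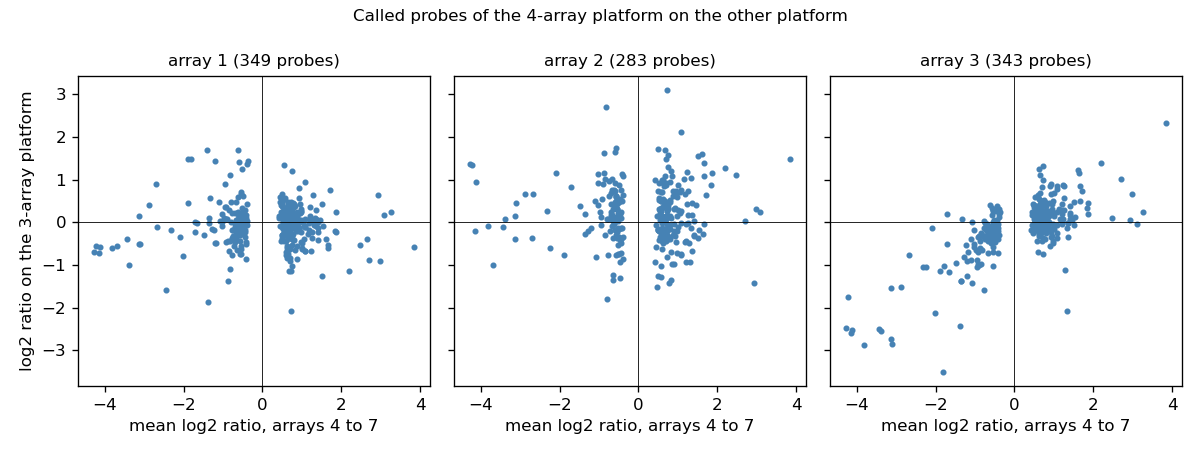
Log2 ratio on array 1, 2 or 3 (y axis) of the probes called on the 4-array platform, against their mean log2 ratio on arrays 4 to 7 (x axis), 1 point per probe. On array 3 73.8% of the points have the same sign on both axes, against 49.0% on array 1 and 49.8% on array 2.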

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

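Chosen only after the result was seen, or after correlations between arrays that largely settle it, were the tests of array 2 turned the wrong way, of a channel bias shared with the 4-array platform or with array 3, of identifiers out of order, and of other sign patterns. The test of brightness was set before its result, but the margin that keeps it open was added after its value was seen.

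Array 2 did not enter the comparison of its platform. Its ratios correlated with those of array 1 at -0.474 across 1144 probes, while neither array correlated with the 4-array platform. Several technical explanations are argued against. If array 2 carried the age difference of the 4-array platform with the wrong sign, it would correlate negatively with the 4-array mean, but it correlated at 0.0172 (95% interval -0.04 to 0.07). A channel bias of single probes shared with the other platform predicts a positive correlation with the contrast between its channel orders, and it was -0.0487 (-0.11 to 0.01). This bears only on a shared bias. A channel bias of arrays 1 and 2 alone was not tested and stays open. Identifiers out of order would break the link between having a value on arrays 1 and 2 and having values on the 4-array platform. Within identifier blocks the weaker of these correlations was 0.431. If shifts of whole identifier blocks made the negative correlation of arrays 1 and 2, centring the blocks would weaken it, but it stayed at -0.442. A wrong turn of array 2 may still be the source of the negative correlation between arrays 1 and 2 and stays open, since turning it makes that correlation positive by construction. Array 3, which follows neither array, correlated with the mean of array 1 and the turned array 2 at 0.0367 (-0.02 to 0.10), which does not decide it. A channel bias that depends on brightness and that 1 scaling constant per array leaves in place may be the source and stays open. With the number of values on the 4-array platform as a coarse stand-in for brightness, the correlation was -0.0696 on array 1 (-0.11 to -0.02) and 0.18 on array 2. These are of opposite sign but weak for this stand-in, which counts values on the other platform only. Whether the ratios of array 1 follow blanks on arrays 2 and 3 was not tested. Different animals behind these arrays are a biological explanation that the labels do not allow to be tested.

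The age ratio differed between the channel orders for 63 probes of the 4-array platform, by a test of the channel term itself. A channel bias shared with array 3, which has the order of arrays 6 and 7, predicts that array 3 sides with these arrays. Given the mean of both orders, the partial correlation of array 3 with their contrast was -0.0129 across 1762 probes (95% interval -0.06 to 0.03). This argues against a bias common to both platforms that is spread over many probes. It was not run on the 63 probes alone, and a shared bias of so few would hardly move it, so for them the question stays open. A bias of this platform alone and a difference between RNA samples stay open, since arrays of the same order may share RNA.

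Of 9 sets of 4 values examined on the 4-array platform, 2 had an extreme value far from the others, where chance gives about 1 in 20. The median of array 7, -0.00267, was nearest to 0, and the other medians lay between -0.0112 and -0.0103. The lowest ratio of array 4 was -7.83, of a probe that arrays 5 and 6 did not measure and that stood at 0.19 on array 7.

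The 801 called probes were set against the other sign patterns of the 4 arrays. Of the 8 patterns, 1 called as many, the real one, and the highest other count was 0. The patterns are too few for a share under 0.05.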

How the results depend on the processing

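Chosen after seeing the data were the random block, the averaging of each channel order, the centring of identifier blocks, the 3-array platform with all its arrays less array 1 or 3, and, between platforms, its arrays alone and the means of all 3. On the 4-array platform the count of 801 called probes stayed within 1.5 times under no centring, quantile or scale normalization, probes on all arrays, arrays 6 and 7 only, robust eBayes, a fold minimum, array weights and centred identifier blocks. Array weights, at 1200 calls, lay at the edge of that bound, and the fold minimum gave 558. Arrays 6 and 7 only gave 593, of which 430 were among the 801. The count was 1319 with a channel term and 1405 on arrays 4 and 5, set against spread within an order. The order as a random block (522) or averaged first (378) allowed for dependence within it. Leaving out each array gave 354 to 645 (474 without array 4, 354 without array 5, 533 without array 6), with fewer arrays by construction and other probes tested. With arrays 4 and 5 turned, limma called 0 probes (141 at an unadjusted p under 0.05); by construction opposite ratios then cancel, RNABJ21 reversed to -0.37 and RGIBA47 to -0.995, and RGIAP58 and RGIAI10 lost their calls. In the other 68 combinations of the 4 named probes with a setting, the direction and the call were kept. The share of positive calls, 55.7%, ranged from 53.8% to 63.1% over the settings with calls. On the 3-array platform the single call remained under quantile normalization, robust eBayes and the fold minimum. With array weights on all 3 arrays 1 probe was called, and it was a different one, since RGIAN79 has no value on array 2; the estimate of these weights stopped before it converged. Limma called 0 probes with no centring (90 at an unadjusted p under 0.05), scale normalization (101), all 3 arrays as deposited (9), with array 2 turned (105), with at least 2 values (38), with a channel term (195), and with array 1 or array 3 left out of the 3 (23 and 5). Leaving out array 1 or 3 from their pair leaves no spread, so it gave no test. Among the 25% of probes with the largest spread between arrays, the mean correlation of opposite channel orders moved from -0.23 to -0.41 on the 3-array platform. This lies past the limit for the other reading, while the ratio steps show array 2 as already turned. Choosing probes by that spread favours probes on which arrays disagree, which by itself can lower the correlation, so the move does not decide the reading. On the 4-array platform the correlation likewise fell, from 0.62 to 0.51. The correlation between platforms, 0.38, was -0.0165 with array 1 alone and 0.0172 with array 2 alone, kept its sign in the other settings, and ranged from -0.0165 to 0.52 with each array left out, the lowest without array 3. No paired analysis was possible because the labels number the arrays 1 to 7 throughout and state no pairing between them. Averaging probes of a gene, taking 1 probe per gene, the gene lists and their alternatives were not run, because no probe could be named.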

Other observations

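The tests of single blocks were chosen only after their calls were seen, as was the comparison of probes by number of arrays. The centring of blocks was added after seeing the data, with its bound set before its result, and the margin that leaves block RNAB open was added after its value was seen.

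Probe identifiers of the 4-array platform fall into 65 blocks of 96 that share a letter prefix, and the called probes were spread unevenly over them. The share of called probes differed between blocks when tested with 10000 permutations of probes over blocks (permutation p = 0.0002), as did the positive and the negative calls taken separately (permutation p = 0.0001 for each, the smallest the permutations can give). In block RNAB 25 of 71 tested probes were called, all of them negative, and 7 of the 23 negative probes of at least 4-fold lay there. In block RGIAE 27 probes were positive and 3 negative. Block RNABJ held 4 of the 23 positive probes of at least 4-fold among only 21 tested. The share of calls was not shown to differ between the identifier series, at 20.3% of 1776 probes for identifiers starting with RGI and 21.7% of 2025 for those starting with RNA (Fisher's exact test, two-sided p = 0.30). Probes measured on all 4 arrays were called more often, at 25.4% of 2591, than those measured on 3, at 11.6% of 1243. A test on 4 values finds a given change more readily than a test on 3, so these shares do not compare how often expression differed.

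A shift of whole blocks, such as a fault of a printing plate, may make calls cluster. Centring each block on its own median on every array gave 839 calls, 690 of them among the 801, and the share of calls still differed between blocks (permutation p = 0.0001; 0.03 for positive and 0.0017 for negative calls), which argues against such shifts as the whole cause. For block RNAB it stays open: its median was -0.31, and centring left 17 of the 25 negative calls and brought 7 positive ones. The medians of blocks RNABJ and RGIAE were 0.40 and 0.24. Their calls after centring were not examined singly, so a shift stays open there too. On the other platform the median of block RNAB was -0.09 on array 1, -0.20 on array 2 and -0.13 on array 3, so a negative median was not particular to the array that follows the 4-array platform. Blocks that hold several probes of the same genes are a further hypothesis, which needs gene names and was not tested.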
